A study of Homo sapiens with 18 samples.

How the data were processed

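Poly(A) RNA of SW480 cells was sequenced in 18 strand-specific libraries. SW480 is an established human colorectal cancer cell line. Per the labels, cells were infected with lentivirus carrying CRISPR/Cas9 and either a control guide (sgNC) or a guide against HSPB1 (sgHSPB1), puromycin was added 48 h after infection for 72 h, and the surviving cells were harvested. Each group holds 3 biological replicates, and each replicate 3 technical libraries, as the sample titles and the library names state. The titles leave the first replicate and the first library of each unnumbered, so replicates and libraries are numbered here 1 to 3 after the library names. The guide sequences and the number of guides are not given in the sources used here. The labels also give no infection date, harvest date or sequencing run, so a culture or run that differed between the groups cannot be separated from the guide.

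The deposited values are FPKM per gene, that is, fragments scaled by transcript length and by the library's mapped total, computed by the authors and stored in a single table of the series. The submitters' processing notes name the GRCh38 genome build, HISAT2 2.0.4, Bowtie2 2.2.5 and StringTie 2.1.2, without the role or order of each. The annotation release, any filter and the strand setting of the quantification are not given in the sources used here. Rows that carry StringTie's own identifiers in place of an Ensembl gene are assembled transcripts that the authors' processing added. Of 24707 rows, 1 had no gene identifier and few values and was left out, and 326 were exact repeats of another row and were counted once. The 24380 rows that remained were 20463 Ensembl genes, 1012 of them without a symbol, and 3917 assembled transcripts. A further 3097 of these rows were at 0 in all 18 libraries. FPKM summed to between 420500 and 433586 per library, and 17844 to 18269 rows were above 0. Low values showed no common step, so the number of fragments per library could not be recovered: the depth is unknown, and no counting interval is given. The 3 biological replicates set the precision of each mean.

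Values were transformed to log2(FPKM + 1), a pseudocount of 1 FPKM. Rows with a mean of at least 1 FPKM over the 18 libraries were tested, 12407 in all (11605 Ensembl genes and 802 assembled transcripts). The 3 technical libraries of a replicate were averaged on the log2 scale, and the 3 sgHSPB1 means were compared with the 3 sgNC means by limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, two-sided, and Benjamini-Hochberg adjustment over all tested rows; the threshold was an adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and the error beside them is the moderated standard error (SE). FPKM means are given with the SD over the 3 replicate means of a group. Whether replicates of a group differed was tested in a second limma model, as an F-test of the 3 replicates against the spread of their technical libraries.

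Before the data were examined, 32 gene lists were fixed, of which 28 had at least 5 tested members. These were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 28 lists. Camera asks whether the genes of a list changed more than other genes did. It was repeated with the correlation estimated per list, and fry, which asks only whether a list's genes move one way on balance, was run beside it. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom, in place of the many that the preset correlation allows. A list can therefore fail that repeat without correlated genes. Counts within lists are given over all tested rows and adjusted over the list alone. All 971 list members were in the table, 2 of them under a newer symbol. Genes were named by a rule fixed at the same time. It takes HSPB1, the 12 largest rises and 12 largest falls among genes past the threshold whose replicate means did not overlap between groups (rows without a gene symbol were passed over), and a panel of 16 immune factors. It also takes the 4 members with the largest change past the threshold from each list past the camera threshold and up to 2 from each other tested list. Of the genes this rule selects, 4 are not reported here and were not replaced; the tests over all rows and over lists include them. Genes named outside this rule, which are regulators or markers of a list (such as HSF1, XBP1, ATF4, SREBF2, EPCAM and LAPTM5) or the few members behind a small count (such as DNAJB9, CCND1, KRT8 and HNF4A), were chosen after their values were seen. Coordinates are from GENCODE release 29 on GRCh38, as are the GC content and transcript length used in a check.

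The model was tested on simulated data before use. In 10 simulations of the sgHSPB1 against sgNC comparison over 12407 rows, each with 200 changed genes and the spread measured here, 34.8% of 1.2-fold changes, 68.0% of 1.3-fold changes, 85.4% of 1.5-fold changes and 95.8% of 2-fold changes were called, and 4.76% of the calls were false. Camera called the single list that was shifted by 0.15 on the log2 scale in all 10 simulations and 0 of the other lists. Simulated genes were independent of each other, so this says nothing about correlated lists. The data gave 3085 calls, far more than the 200 changed genes simulated, so the adjusted threshold lay at a larger unadjusted p in the data. The shares found and the share of false calls are therefore those of the simulation and not of this comparison.

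Alternatives fixed before the data were examined were a pseudocount of 0.1 FPKM, no filter and a filter of 5 FPKM, rescaling to TPM, median-of-ratios factors, quantile normalization, all 18 libraries with the replicate as a random effect (duplicateCorrelation, with statmod 1.5.0), each technical library alone, limma without the trend, a block on the replicate number, and leaving out each replicate in turn. Chosen after the data were seen were Ensembl genes alone, a removal of each replicate's trend with GC content and transcript length (loess with a span of 0.5), the TPM and median-of-ratios scalings for the gene lists, and 6 further gene lists.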

Results

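Gene expression was measured by poly(A) RNA sequencing in SW480 human colorectal cancer cells that carried a control guide (sgNC) or a guide against HSPB1 (sgHSPB1). HSPB1 encodes the small heat shock protein HSP27. The series title names HSPB1 targeting, tumour growth and immunosuppression by regulatory T cells as its subject, and the design gives a single comparison, sgHSPB1 against sgNC, with 3 biological replicates per group and 3 technical libraries per replicate. The deposited FPKM summed to 420500 to 433586 per library, with 12284 to 12466 rows at 1 FPKM or more, and the sequencing depth is unknown. Markers of leukocytes, fibroblasts and endothelium were nearly absent. Of 20 leukocyte markers, 3 passed the filter of 1 FPKM (LAPTM5, CORO1A and CD68), as did 2 of 18 fibroblast and endothelial markers (EGFL7 and COL1A1), and none of these 5 genes changed over all tested rows in the limma model (adjusted p = 0.054 for LAPTM5, 0.0757 for CORO1A). Adjusted over the list alone, 1 leukocyte marker was higher (CORO1A at 0.11) and 1 lower (LAPTM5 at −0.20).

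The biological replicates of a group differed little more than the technical libraries of a replicate did. The median SD of log2(FPKM + 1) was 0.094 between technical libraries, and 0.057 between the replicate means of a group, against the 0.054 that technical scatter alone gives for means of 3 libraries. In a limma F-test of replicates against technical libraries, 3 of 12407 rows differed between the sgNC replicates (631 at an unadjusted p below 0.05) and 51 between the sgHSPB1 replicates (1349 unadjusted). The p-values below measure only the spread between these samples. The labels call the 3 replicates of a group biological but do not say whether they were separate infections or cultures of a single infected pool, and in the latter case n = 3 covers culture and library preparation alone. The first principal component held 17.9% of the variance and separated the groups. The sgNC replicates averaged −8.14, −11.4 and −10.6 on it, and the sgHSPB1 replicates 4.74 (replicate 1), 11.4 and 14.1.

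HSPB1 mRNA was higher in the libraries labelled sgHSPB1, which is opposite to a loss of the targeted transcript. HSPB1 (ENSG00000106211, GRCh38 chromosome 7, 76302544 to 76304295, plus strand, protein coding) had 157 ± 6.75 FPKM in sgNC (SD, n = 3 replicates) and 193 ± 8.30 FPKM in the libraries labelled sgHSPB1 (SD, n = 3), 23% more. The replicate means were 165, 154 and 153 FPKM in sgNC and 189, 188 and 203 FPKM in sgHSPB1. Of the 9 libraries labelled sgHSPB1, 7 lay above the highest sgNC library, at 180.6 FPKM. The log2 fold change was 0.30 (SE 0.045, limma adjusted p = 0.00683), and an exact two-sided permutation test of the 6 replicate means gave p = 0.1, the smallest that 20 arrangements allow. With technical library 1 alone or 3 alone the rise was 0.30 and 0.22 and no longer passed (limma adjusted p = 0.151 and 0.16). A transcript level does not show whether a guide edited the gene or removed the protein, which was not measured here. Because the target runs against its label, each direction below is stated for the libraries labelled sgHSPB1. The other members of the small heat shock protein list above the filter were HSPB8 and IFT25 (formerly HSPB11), with log2 fold changes of 0.02 and 0.09 and limma adjusted p of 0.854 and 0.299. Of 15 tested neighbours of HSPB1 on 7q11.23, 2 were lower (GSAP at −0.20, PTPN12 at −0.12) and 13 did not pass (2 lower adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.517). GSAP was not past the threshold without sgNC replicate 2 or 3 or sgHSPB1 replicate 2 (−0.18 to −0.22, limma adjusted p up to 0.0697), and PTPN12 without any single replicate (−0.10 to −0.13, up to 0.0862).

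In the libraries labelled sgHSPB1, where HSPB1 itself was higher, many genes moved by small amounts. In limma, 3085 of 12407 rows (24.9%) changed, 1573 higher and 1512 lower, with a median absolute change among them of 1.16-fold. At least 1.5-fold was reached by 99 of them and at least 2-fold by 13, of which 11 were lower. The 2-fold count was 26 without sgHSPB1 replicate 1 and 33 with a pseudocount of 0.1 FPKM. The 2 that were higher and 3 of those lower were assembled transcripts without a gene name. Replicate means of the groups did not overlap for 45.2% of rows, against 10% by chance. The count depended on which replicate was left out and on the averaging over technical libraries. It fell to between 1358 and 1959 when any replicate other than sgHSPB1 replicate 1 was left out, and was 2946 without that replicate; with a single technical library per replicate it was 410, 747 or 671.

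**Figure D1:**
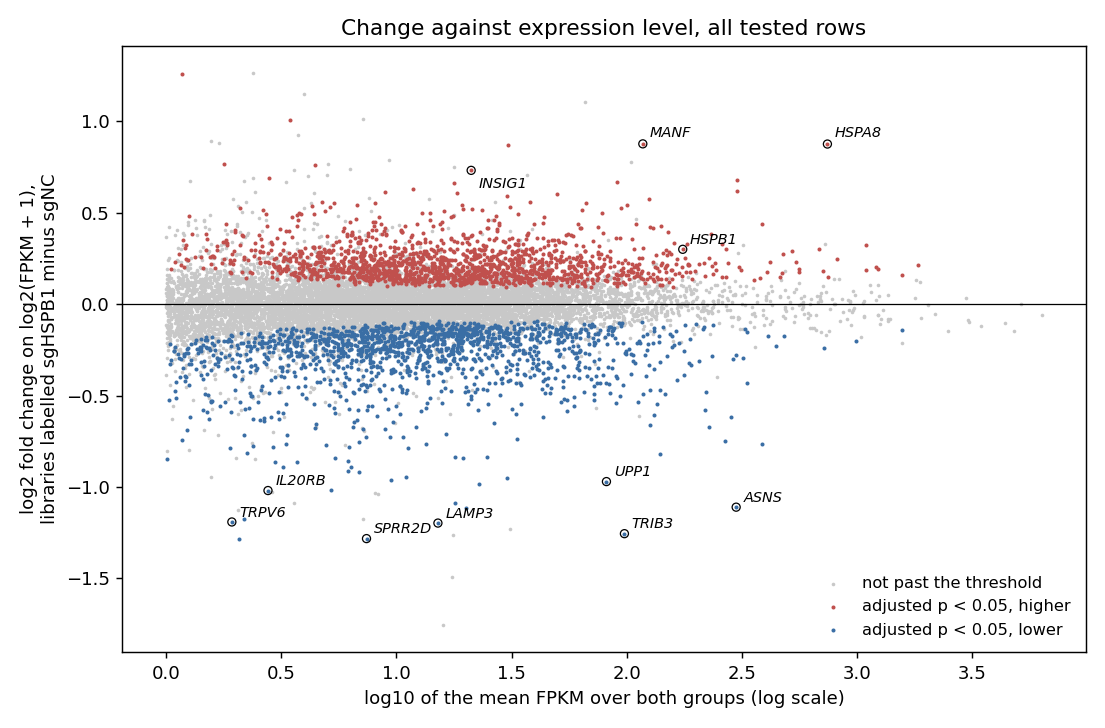
Log2 fold change on log2(FPKM + 1), libraries labelled sgHSPB1 minus sgNC, against the log10 of the mean FPKM over both groups, with a point for each of the 12407 tested rows (red, higher; blue, lower; grey, not past the threshold). HSPB1 lies above 0 at 0.30, most changes past the threshold are small, and the named genes with the largest falls, such as SPRR2D at −1.28 and TRIB3 at −1.26, are further from 0 than those with the largest rises, such as MANF at 0.88.

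Among named genes, the largest rises in the libraries labelled sgHSPB1 were mostly of chaperones and of genes of cholesterol synthesis. MANF, an ER stress-induced secreted protein, went from 82.4 ± 1.99 to 153 ± 16.6 FPKM (log2 fold change 0.88, SE 0.076, limma adjusted p = 0.00259). HSPA8, the constitutive cytosolic HSP70, went from 522 ± 15.1 to 969 ± 184 FPKM (0.88, SE 0.13, p adjusted 0.00658). The 11 named rises also held SDF2L1, HSPA5 and CALR of the ER, the chaperone HSPH1, INSIG1, HMGCS1 and IDI1 of the sterol pathway, ORC1 of the replication origin complex and DYNC1I2, a dynein chain, with log2 fold changes between 0.61 and 0.87. The rise of DYNC1I2, at 0.63, rests on few libraries. It was 0.07 with technical library 1 alone and 0.74 with library 2 alone, both not past the threshold, and 1.07 with library 3 alone, and single libraries ranged from 3.45 to 21.4 FPKM. On the log2(FPKM + 1) scale, the largest named falls were of SPRR2D, a cornified envelope protein, from 10.9 ± 1.45 to 3.92 ± 0.503 FPKM (−1.28, SE 0.10, p adjusted 0.00259), and of TRIB3, a pseudokinase induced by ATF4, from 137 ± 4.14 to 58.6 ± 18.7 FPKM (−1.26, SE 0.20, p adjusted 0.00777). In percent of FPKM the low gene TRPV6 fell further, from 3.07 ± 0.222 to 0.786 ± 0.200 FPKM (−74.4%, against −64% for SPRR2D). LAMP3, the calcium channel TRPV6, ASNS, NIBAN1, the receptor subunit IL20RB, the adaptor GRB10, the uridine phosphorylase UPP1, the cystine transporter SLC7A11 and the mitochondrial PCK2 had log2 fold changes between −0.95 and −1.198. BEST1 was also lower, at −1.115, but its exons overlap those of FTH1 on the other strand. The strand setting of the quantification is not known, so its value is uncertain, and the call was lost with all 18 libraries and with each technical library alone (−0.33 to −2.50 over the alternatives). Exons of other named genes also overlap a gene on the other strand, such as those of KIF20A, PSMD13, ARG2, GINS2, FEN1, TNFRSF10B, TGFB1 and ACTA2. The unknown strand setting bears on their values too. IL20RB and ASNS share exon positions with another gene on the same strand.

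Chaperones regulated by HSF1, the heat shock transcription factor, rose together in the libraries labelled sgHSPB1. The list is not limited to the cytosol and also holds HSF1 and HSF2 themselves. Of 25 tested members, 16 were higher, 0 lower and 9 not past the threshold over all rows (18 higher adjusted over the list alone), with a median log2 fold change of 0.33. HSPH1 rose from 70.1 ± 1.40 to 112 ± 9.16 FPKM (0.67), and DNAJA1, a J-domain co-chaperone, from 81.9 ± 0.804 to 120 ± 4.16 FPKM (0.54), both at a limma adjusted p of 0.00259. HSPA1A, at 2.92 ± 0.250 and 4.60 ± 1.04 FPKM, also passed (0.50, p adjusted 0.033). Whether reads of the near-identical HSPA1B contribute to the HSPA1A value was not tested, so that value is uncertain. Without any sgNC replicate or without sgHSPB1 replicate 2, HSPA1A did not pass (0.45 to 0.54, limma adjusted p 0.0632 to 0.0994). HSF1 itself was at 0.00 (p adjusted 0.996). The list passed camera with the preset correlation (adjusted p = 1.53e-08) and did not with an estimated correlation (adjusted p = 0.376).

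ER chaperones of the unfolded protein response rose as well: 16 of 21 tested members were higher, 1 lower and 4 not past the threshold (the same counts adjusted over the list alone), with a median of 0.27. HSPA5 (BiP), the main ER HSP70, rose from 230 ± 8.71 to 371 ± 53.6 FPKM (0.68, SE 0.10, limma adjusted p = 0.0068). SDF2L1 rose from 21.4 ± 2.57 to 39.6 ± 4.38 FPKM (0.87), and the calcium-binding chaperone CALR from 238 ± 10.1 to 367 ± 28.3 FPKM (0.62). The exception was DNAJB9, which was lower by 0.41 (p adjusted 0.00487); the transcription factor XBP1 was at −0.06 (p adjusted 0.382). Camera gave an adjusted p of 2.97e-07, and 0.451 with an estimated correlation. Proteasome subunits moved less. Of 31, 11 were higher and 0 lower, 20 not past the threshold (13 higher adjusted over the list alone), with a median of 0.09. PSMD13 rose from 106 ± 5.51 to 131 ± 5.76 FPKM (0.30), PSMD11 from 69.5 ± 2.73 to 84.5 ± 2.01 FPKM (0.27), and PSMD6 and PSMD4 each by 0.22 on the log2 scale. Without sgHSPB1 replicate 2, PSMD6 did not pass (0.22, p adjusted 0.0543), and PSMD11 did not with any technical library alone (0.22 to 0.35, p adjusted up to 0.261). PSMD4 did not pass with technical library 1 or 2 alone (p adjusted up to 0.175), nor PSMD13 with library 2 alone (0.11). The list passed camera (adjusted p = 0.000907), but not with an estimated correlation (adjusted p = 0.376).

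Genes that ATF4 induces in amino acid shortage and the integrated stress response fell in the libraries labelled sgHSPB1. Of 25 tested members, 14 were lower, 1 higher and 10 not past the threshold (16 lower and 1 higher adjusted over the list alone), with a median log2 fold change of −0.32. ASNS, the asparagine synthetase, fell from 408 ± 17.9 to 191 ± 37.3 FPKM (−1.11, SE 0.13, limma adjusted p = 0.00348). PSAT1 of serine synthesis fell from 337 ± 5.95 to 201 ± 27.5 FPKM (−0.75, p adjusted 0.00396), and SLC7A11 from 12.8 ± 0.683 to 6.20 ± 1.65 FPKM (−0.96, p adjusted 0.0077). ATF4 mRNA was lower by 0.28 (327 ± 1.92 to 270 ± 25.0 FPKM, p adjusted 0.0234), while DDIT3 (CHOP) did not pass at 0.05 (p adjusted 0.745). The member that rose was CHAC1, a glutathione-degrading enzyme, from 14.2 ± 0.674 to 20.2 ± 2.16 FPKM (0.48). Camera gave an adjusted p of 4.12e-05, and 0.513 with an estimated correlation. Fry did not call the list (adjusted p = 0.0524).

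**Figure D2:**
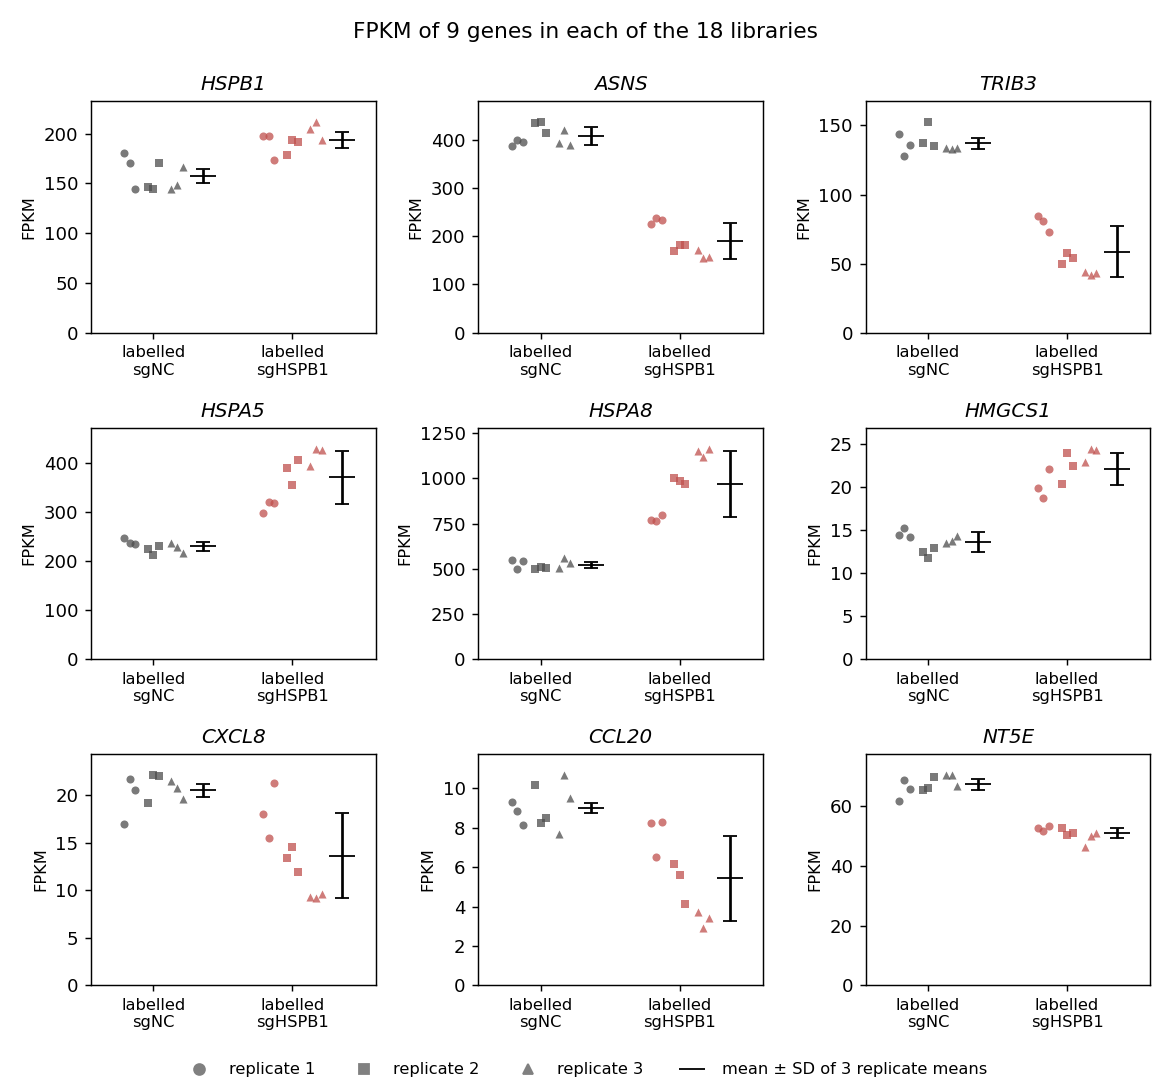
FPKM (linear axes from 0) of 9 genes in each of the 18 libraries, by labelled group; marker shapes give the biological replicate, and the bar with caps is the mean ± SD of the 3 replicate means. HSPB1 is higher in the libraries labelled sgHSPB1 (193 against 157 FPKM), ASNS and TRIB3 are lower in all 9 of them than in any sgNC library, and CXCL8 and CCL20, which did not pass the threshold, are lower on average but overlap in replicate 1.

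Genes of cholesterol synthesis and uptake rose in the libraries labelled sgHSPB1. Of 25 tested members, 18 were higher and 0 lower, 7 not past the threshold (19 higher adjusted over the list alone), with a median of 0.37. INSIG1, a sterol sensor of the ER, rose from 15.6 ± 0.387 to 26.7 ± 3.48 FPKM (0.73), HMGCS1, the cytosolic HMG-CoA synthase, from 13.6 ± 1.12 to 22.1 ± 1.86 FPKM (0.66), and IDI1 from 14.4 ± 1.12 to 22.4 ± 0.804 FPKM (0.61), all with a limma adjusted p between 0.00259 and 0.00396. The regulator SREBF2 was at 0.03 (p adjusted 0.565). Camera gave an adjusted p of 3.62e-11, and 0.376 with an estimated correlation. In the fatty acid list, 9 of 29 members were higher and 2 lower, 18 not past the threshold (13 and 3 adjusted over the list alone), with a median of 0.08. FASN, the fatty acid synthase, rose from 23.9 ± 1.04 to 36.6 ± 4.15 FPKM (0.59), the binding protein FABP5 from 64.2 ± 2.71 to 86.3 ± 2.67 FPKM (0.42), the oxidation enzyme HADH by 0.27 and the desaturase SCD by 0.25 on the log2 scale. That list passed camera at 0.0315, not with an estimated correlation (adjusted p = 0.47), and lost the call under quantile normalization (0.0528), under a 5 FPKM filter (0.062) and without sgNC replicate 2 (0.0674) or sgHSPB1 replicate 3 (0.056).

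Cell division genes were higher in the libraries labelled sgHSPB1. Among G1/S and DNA replication genes, 32 of 40 were higher, 0 lower and 8 not past the threshold (35 higher adjusted over the list alone), with a median of 0.24. UHRF1, a DNA methylation maintenance factor, rose from 25.2 ± 1.05 to 36.9 ± 2.12 FPKM (0.53), GINS2 and the helicase subunit MCM4 each by 0.50, and the flap endonuclease FEN1, which shares exon positions with FADS2, by 0.42 on the log2 scale. Among G2/M and mitosis genes, 37 of 45 were higher, 0 lower and 8 not past the threshold (40 higher adjusted over the list alone), with a median of 0.21. The kinesin KIF20A rose from 30.5 ± 1.62 to 45.5 ± 3.21 FPKM (0.56), CDC20 from 112 ± 4.74 to 149 ± 7.02 FPKM (0.41), and CDCA2 and DLGAP5 each by 0.38 on the log2 scale. Camera gave adjusted p of 1.7e-15 and 1.87e-15 for the lists, against 0.376 and 0.381 with an estimated correlation. The p53 targets held 4 lower members of 27 and 0 higher, with 23 not past the threshold (4 lower adjusted over the list alone, and camera adjusted p = 0.206). The share of lower members was close to that of all tested rows, 1512 of 12407. Among the 4 were EDA2R at −0.44 and the death receptor TNFRSF10B at −0.40. With technical library 1 alone neither of these passed, EDA2R not with library 3 alone and TNFRSF10B not with library 2 alone (limma adjusted p up to 0.0799 and 0.0879).

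Wnt and beta-catenin targets moved mostly up. SW480 carries a truncating APC mutation and has active Wnt signalling as background. In the libraries labelled sgHSPB1, 14 of 26 members were higher, 2 lower and 10 not past the threshold (15 and 2 adjusted over the list alone), with a median of 0.18. SP5 rose from 15.8 ± 0.304 to 23.2 ± 2.34 FPKM (0.52), the feedback inhibitor NKD1 from 13.2 ± 0.469 to 18.4 ± 0.844 FPKM (0.45) and the intestinal stem cell factor ASCL2 by 0.41 on the log2 scale (not past the threshold with any technical library alone, p adjusted up to 0.159). The 2 that fell were the proliferation genes MYC, from 189 ± 8.43 to 142 ± 7.97 FPKM (−0.41, limma adjusted p = 0.00437), and CCND1 (−0.18, p adjusted 0.0118). Camera gave an adjusted p of 0.000311, and 0.451 with an estimated correlation.

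NF-kB inflammatory targets and several epithelial junction genes fell in the libraries labelled sgHSPB1. Of 25 NF-kB targets, 13 were lower, 0 higher and 12 not past the threshold (16 lower adjusted over the list alone), with a median of −0.23. TNFAIP2 fell from 52.8 ± 1.24 to 34.2 ± 3.79 FPKM (−0.62), the inhibitor of apoptosis BIRC3 from 15.6 ± 0.782 to 10.1 ± 1.23 FPKM (−0.58), the siderophore-binding LCN2 from 263 ± 20.5 to 176 ± 10.04 FPKM (−0.58), and the acute-phase SAA2, which shares exons with the readthrough gene SAA2-SAA4, from 29.8 ± 3.43 to 20.04 ± 1.19 FPKM (−0.55), with limma adjusted p between 0.00348 and 0.00762. Camera gave an adjusted p of 4.11e-07, and 0.452 with an estimated correlation. Of 26 epithelial junction and keratin genes, 9 were lower, 1 higher and 16 not past the threshold (10 and 1 adjusted over the list alone), with a median of −0.09. The tight junction protein CLDN1 fell from 13.5 ± 0.206 to 7.83 ± 1.07 FPKM (−0.73), the epithelial splicing factor ESRP1 from 52.0 ± 0.871 to 38.0 ± 1.45 FPKM (−0.44), and the keratins KRT80 and KRT7 were lower, at −0.40 and −0.37; KRT7 did not pass with any technical library alone (p adjusted up to 0.108). The member that rose was KRT8 (0.21), and EPCAM (−0.07) and CDH1 (−0.06) did not pass. Camera gave an adjusted p of 0.00829, and 0.376 with an estimated correlation.

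The question that the series title raises, factors that attract or act through regulatory T cells, was addressed by a list and a panel of genes fixed beforehand, of which 14 panel genes are reported. In the libraries labelled sgHSPB1, 6 of 23 tested members of the list were lower, 0 higher and 17 not past the threshold (6 lower adjusted over the list alone), and the list as a whole did not pass camera (adjusted p = 0.206; median −0.02). Fry, which asks only whether its genes move one way on balance, gave an adjusted p of 0.00474 for a downward shift. The arginase ARG2 fell from 62.8 ± 1.04 to 43.8 ± 4.40 FPKM (−0.52, limma adjusted p = 0.00464), and the growth factor CSF2 from 18.2 ± 1.72 to 12.96 ± 2.27 FPKM (−0.48, p adjusted 0.0376). The CSF2 call was lost without any single replicate but sgHSPB1 replicate 1 (−0.34 to −0.52, p adjusted 0.0561 to 0.111). In the panel, NT5E (CD73), which makes adenosine, fell from 67.2 ± 1.89 to 51.0 ± 1.72 FPKM (−0.39, SE 0.037, p adjusted 0.00259; 0.0502 with technical library 1 alone), and VEGFA from 22.0 ± 0.143 to 17.7 ± 1.78 FPKM (−0.30, SE 0.066, p adjusted 0.0216). VEGFA did not pass without any sgNC replicate or without sgHSPB1 replicate 2 (−0.29 to −0.31, p adjusted 0.0577 to 0.0632). CD274 (PD-L1) was at 1.15 ± 0.0605 and 0.857 ± 0.145 FPKM and did not pass (−0.21, p adjusted 0.0766). The chemokines CCL20, at 9.01 ± 0.266 and 5.44 ± 2.17 FPKM (−0.70, p adjusted 0.0626), and CXCL8, at 20.5 ± 0.690 and 13.6 ± 4.47 FPKM (−0.60, p adjusted 0.0679), did not pass either. These 3 calls depended on the processing. Without sgHSPB1 replicate 1 all 3 passed, CCL20 at −0.94 (p adjusted 0.0108), CXCL8 at −0.82 (0.0112) and CD274 at −0.27 (0.0388). With all replicates they passed once GC and length trends were removed (0.0406, 0.0462 and 0.0462), and in the limma model of the 18 libraries (0.00141, 0.00141 and 0.00823). That model used a correlation of 0.0287 within replicates for all rows, so it took technical libraries as nearly independent. The means of sgHSPB1 replicates 1 to 3 were 7.67, 5.30 and 3.35 FPKM for CCL20 and 18.3, 13.3 and 9.37 FPKM for CXCL8. Its p-values for these 2 genes therefore do not measure the spread between replicates. Adjusted p over all alternatives ran from 0.00141 to 0.234 for CCL20, 0.00141 to 0.224 for CXCL8 and 0.00823 to 0.715 for CD274. TGFB1 was at 18.05 ± 0.465 and 19.3 ± 0.416 FPKM (0.09, p adjusted 0.088), and B2M (−0.11, p adjusted 0.065, but 0.038 under quantile normalization) and CCL28 (−0.02, 0.846) did not pass. MIF ranged from 3.83 to 140 FPKM between single libraries and did not pass (0.78, p adjusted 0.304). CCL22, CCL5, IL6, IL18 and LGALS9 averaged under the filter, at 0.0231, 0.0898, 0.0188, 0.0984 and 0.405 FPKM in sgNC and 0.0134, 0.0460, 0.00503, 0.0222 and 0.383 FPKM in the libraries labelled sgHSPB1.

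**Figure D3:**
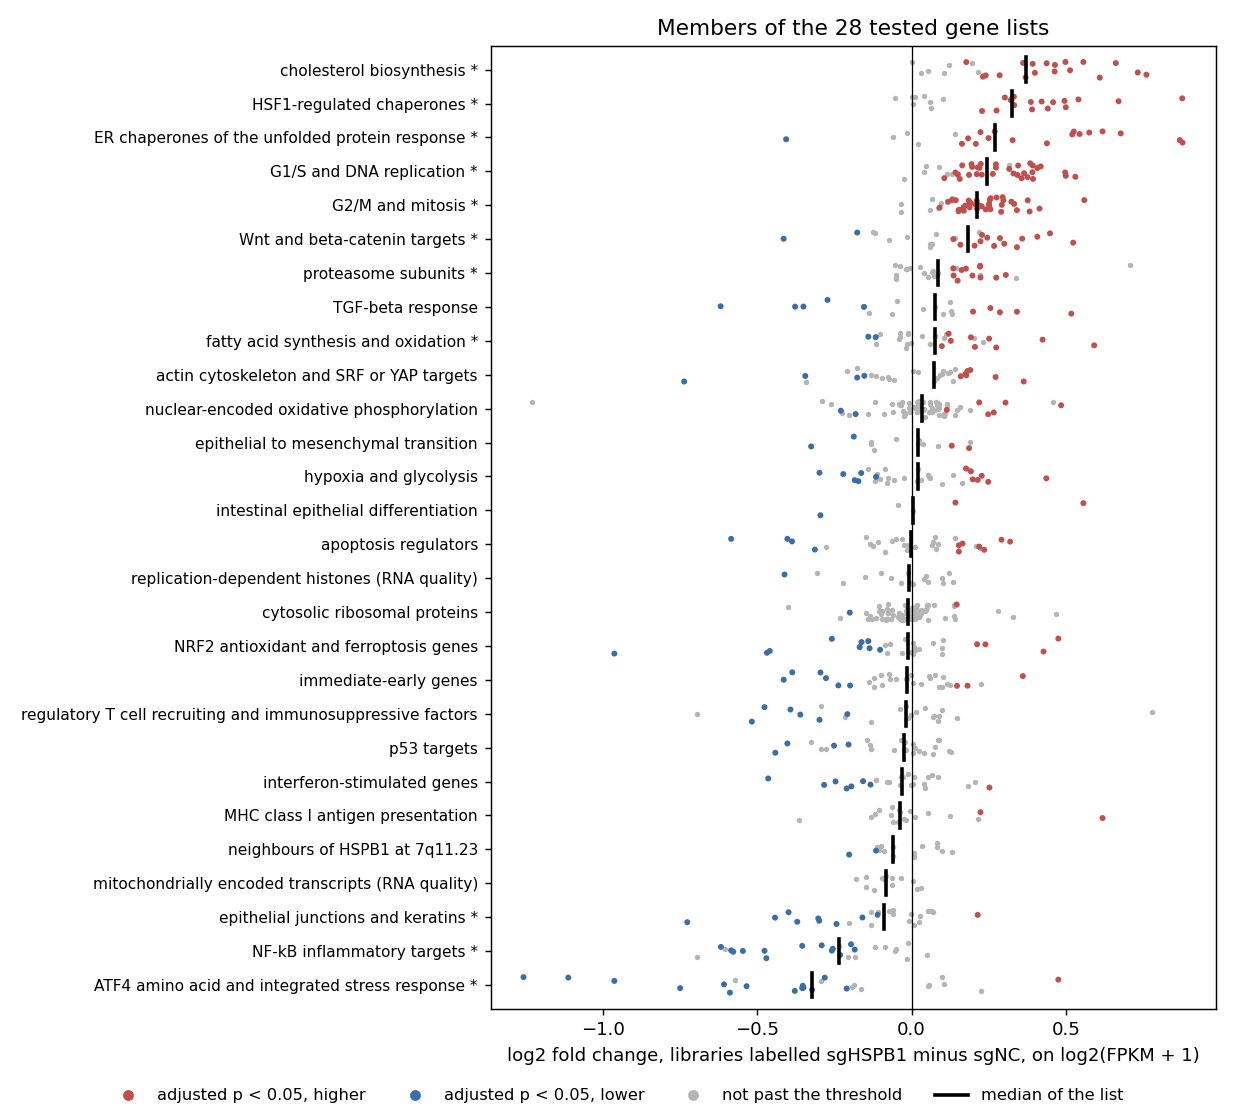
Log2 fold change on log2(FPKM + 1), libraries labelled sgHSPB1 minus sgNC, of the tested members of the 28 gene lists, with a point for each gene (red, higher; blue, lower; grey, not past the threshold) and a black bar at each list's median; an asterisk marks the 11 lists past the camera threshold with the preset correlation, of which 0 passed with an estimated correlation. The 5 lists with the highest medians are of cholesterol synthesis, chaperones and cell division, at 0.37 to 0.21, and the lowest median is that of ATF4 targets, at −0.32.

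The other lists with at least 5 tested members did not pass camera in either direction. Interferon-stimulated genes held 7 lower and 1 higher member of 26, with 18 not past the threshold (the same counts adjusted over the list alone; camera adjusted p = 0.232), among them ISG20 at −0.46 and RIGI at −0.28. The ISG20 call was lost without any single replicate but sgNC replicate 1 and sgHSPB1 replicate 1 (−0.39 to −0.48, limma adjusted p up to 0.0679), and that for RIGI without sgNC replicate 1 or 3 (−0.26 and −0.28, up to 0.0547). MHC class I genes held 2 higher of 19 and 0 lower, CALR and PDIA3, which are also ER chaperones (1 adjusted over the list alone; 0.828), and PDIA3 did not pass without any single replicate but sgHSPB1 replicate 1 (0.17 to 0.25, limma adjusted p 0.0715 to 0.115). The MHC class II list, with 4 tested members, was under the minimum of 5 set for the fixed lists and was not tested with camera. IFI30 was higher (0.38) and CTSS lower (−0.24), and adjusted over the list alone 1 was higher and 2 lower. TGF-beta response genes split 5 higher to 5 lower of 19 (8 and 6 adjusted over the list alone; 0.748): ID2 rose from 52.6 ± 2.21 to 75.8 ± 5.31 FPKM (0.52). Genes of the epithelial to mesenchymal transition split 2 to 2 of 13 (3 and 2; 0.956), with SNAI2 at −0.33 and ACTA2 at −0.19, both not past the threshold without sgNC replicate 2 or 3 or sgHSPB1 replicate 2 or 3 (−0.27 to −0.34 and −0.15 to −0.21), and ACTA2 also not without sgNC replicate 1 (−0.16). Apoptosis regulators held 7 higher and 4 lower of 32 (10 and 5; 0.775), NRF2 and ferroptosis genes 4 higher and 9 lower of 28 (5 and 10; 0.385), hypoxia and glycolysis genes 7 and 6 of 32 (10 and 8; 0.861; ADM at 0.44), and immediate-early genes 3 and 6 of 31 (4 and 6; 0.621; FOSL1 at −0.39, lost without sgNC replicate 2 or 3 or sgHSPB1 replicate 2, at −0.32 to −0.40). Among actin and SRF or YAP targets 7 were higher and 4 lower of 31 (8 and 5; 0.601), where the receptor AXL fell from 41.8 ± 1.72 to 24.7 ± 1.97 FPKM (−0.74, limma adjusted p = 0.00259) and CNN2 rose by 0.36 on the log2 scale. Of 5 tested intestinal differentiation genes 2 were higher, CDX2 (0.56) and HNF4A (0.14), and KLF4 was lower (−0.30; the same counts adjusted over the list alone; list 0.775). KLF4 did not pass without any sgNC replicate or without sgHSPB1 replicate 2 (−0.28 to −0.32). Cytosolic ribosomal proteins were nearly level, with RPS15 higher and RPL3 lower of 74 (0 adjusted over the list alone; 0.579), and both calls were lost without sgNC replicate 2 or 3 or sgHSPB1 replicate 2 or 3 (RPL3 −0.17 to −0.21, RPS15 0.11 to 0.16), that of RPS15 also without sgHSPB1 replicate 1 (0.15). Nuclear-encoded oxidative phosphorylation genes held 6 higher and 2 lower of 66 (4 and 1; 0.196), with NDUFB10 at 0.48 (not past the threshold with all 18 libraries or with any technical library alone, 0.22 to 0.87 over the alternatives) and ATP5MC1 at 0.30. As measures of RNA quality, 0 of 13 mitochondrially encoded transcripts changed (0 adjusted over the list alone; 0.43, but 0.0146 with a median of −0.21 without sgNC replicate 3), and they made up 7.38% to 10.03% of the FPKM sum in sgNC libraries and 6.93% to 8.74% in those labelled sgHSPB1. Of 17 replication-dependent histone genes, H2AC6 alone changed (−0.41; 1 adjusted over the list alone; list 0.565). Median and mean differed in sign for MHC class I (−0.04 and 0.01), mesenchymal (0.02 and −0.02) and actin genes (0.07 and −0.01). For apoptosis regulators camera pointed up, while median and mean were −0.00 and −0.01. Further calls that were not past the threshold with a single technical library per replicate were those of SDF2L1, PCK2, SP5, FEN1, ADM, FASN, CNN2, CDX2 and ATP5MC1 with library 1, SAA2, FABP5 and SCD with library 2, and ID2, HADH, SCD and ATP5MC1 with library 3.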

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

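The tests of a rise shared with other chaperones, of an exchange of both labels and of a single share of unchanged cells were chosen after the results were seen; the others were written before.

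In the libraries labelled sgHSPB1, HSPB1 mRNA was higher, by 0.30 on the log2 scale. The scaling of the values does not account for it: the lowest change under TPM rescaling, median-of-ratios factors and quantile normalization was 0.286. A single exchanged library or replicate is argued against as well, since 0 of the 18 libraries correlated better with the mean profile of the other group than with that of their own. Whether the rise is shared with the other chaperones that HSF1 regulates stays open: 40% of the 25 tested members of that list had a lower log2 fold change than HSPB1, but the list's 10th and 90th percentile, at 0.01 and 0.52, also enclose 48.7% of all tested rows, so the position of HSPB1 among them decides nothing. An exchange of the 2 groups' labels as a whole cannot be told apart from a guide that left the transcript in place, because HSPB1 itself, at 0.30, is the only value here that bears on it, and protein and edited alleles were not measured.

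The change differed between the sgHSPB1 replicates, and was smaller in replicate 1. Over the 11 lists past the camera threshold, its mean change was on average 0.67 of that of replicates 2 and 3, and it was below theirs in 10 of the 11. Replicate 3 was as far on the other side, at 1.46 of replicates 1 and 2, and replicate 2 was at 1.02 of replicates 1 and 3, so replicate 1 does not stand alone. An odd technical library is argued against, since leaving out any of its 3 libraries left the average at no more than 0.703. A single share of unchanged cells in replicate 1 stays open. The share was 0.35 for ATF4 targets, 0.40 for NF-kB targets and 0.79 for G1/S genes, more apart than technical spread gave in 2000 random draws of whole libraries. The draws hold no differences between biological replicates, however, and 1 of the other 2 replicates, replicate 3, showed shares that differed between lists in the same way. A single share therefore cannot be told apart from ordinary differences between replicates. A replicate that differed in culture state, which the labels do not record, stays open too. The labels give the same times for all replicates, with puromycin added 48 h after infection for 72 h. No biological explanation was tested, since the design gives no group within the replicates.

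Cell division genes were higher in the libraries labelled sgHSPB1, where HSPB1 was higher too. GC content and transcript length do not account for this, since the median of the 85 tested genes was 0.219 as deposited and 0.226 once each replicate's trend with both was removed. Scaling does not either, since the lowest median under the 3 other scalings was 0.215. The guide, named by the design, and a culture that grew or was seeded differently both stay open, as untested. All 3 replicates of a group share the guide, and the labels do not say whether they also shared a culture. The fall of MYC and CCND1 beside it (−0.41 and −0.18) is a measured exception to a rise of proliferation genes.

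For the count of changed genes, the 6 replicates can be split in only 10 ways, too few for a share under 0.05. The real split, 1 of 10 with a result as large, called 3085 genes and the highest of the other splits 1. At 2-fold the values were 13 and 1, again with 1 split as large. For the gene lists, 3 of the 10 splits gave as many lists past the camera threshold with the preset correlation. The real one gave 11, and the others gave 4 to 14. The number of lists past camera with the preset correlation therefore does not set the real split apart from the others. Each of the other 9 splits sets 2 replicates of a group and 1 of the other against the rest, and so keeps part of the group difference. That difference also enters the spread within each side of such a split. Once the groups differ, few called genes are therefore fixed in advance there, and the low counts do not measure chance.

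Among 194 sets of 9 libraries (named genes and library measures in each group), 10 held a library set apart from the other 8, against about 10 by chance. The gap as a share of the range was 0.749 for PSMD4 in sgNC (replicate 1, library 1, at 122 FPKM against at most 105), 0.532 for FABP5 in sgNC (54.5 against at least 61.9), 0.6 for H2AC6 in sgNC (38.2 against at most 35.9) and 0.573 for IL6 in sgNC (0.118 against at most 0.0506). In sgHSPB1 it was 0.532 for UPP1 (66.2 against at most 56.9), 0.534 for PSMD13 (116 against at least 127), 0.527 for TGFB1 (21.7 against at most 19.8), 1 for IL6 (0.0453, with the other 8 at 0), 0.642 for LGALS9 (0.859 against at most 0.459) and 0.534 for NT5E (46.4 against at least 50.1). Without the library concerned, PSMD4, FABP5, H2AC6, UPP1, PSMD13 and NT5E stayed past the limma threshold in the same direction, with adjusted p between 0.00216 and 0.00606, and TGFB1 moved from 0.09 to 0.07, not past it in either case.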

How the results depend on the processing

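All alternatives here were fixed before the data were examined except Ensembl genes alone, the removal of GC and length trends, and the TPM and median-of-ratios scalings of the gene lists. The rise of HSPB1 kept its direction under all 20 alternatives, between 0.22 and 0.38, and passed under 18 of them (limma adjusted p from 0.000183 to 0.16); it did not with technical library 1 alone (0.304) or 3 alone (0.217). The count of 3085 changed genes stayed within 1.5 times under other pseudocounts, filters and scalings (2369 to 3158). The same held without the trend (2979), with all 18 libraries (4298), with Ensembl genes alone (3198) and with GC and length trends removed (3467). The 4298 come from a model that took technical libraries as nearly independent (correlation of 0.0287 within replicates). The genes called were not all the same. With no filter, which tested 21283 rows, 2023 of the 3085 calls were kept, and 11 of the 80 named calls were lost. A single library per replicate gave 410 genes (181 higher, 229 lower), 747 (293 and 454) or 671 (314 and 357), where by construction each of the 6 replicate values rests on 1 library and not on the mean of 3. Leaving out 1 replicate gave 1358 to 2946 changed genes, 626 to 1531 higher and 732 to 1415 lower, 12 to 26 at 2-fold, an HSPB1 change of 0.27 to 0.33, and 10 to 12 lists. The 13 genes at 2-fold became 33 with a pseudocount of 0.1, which shrinks low genes less. They became 25 after TPM rescaling, which raised all values while the pseudocount stayed the same, so low genes were shrunk less there too. With technical library 3 alone they became 24, and the cause was not tested. The 13 genes became 8 with Ensembl genes alone and 8 with GC and length trends removed, which leave out the 5 assembled transcripts among them.

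With a replicate block the count was 1677 (806 higher and 871 lower), and 11 lists passed. The numbers do not pair the samples. The deviations of same-numbered replicates from their group means correlated at −0.061, −0.066 and −0.028 over genes, and no sample correlated best with its own number.

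Of 80 named genes past the threshold besides HSPB1, 40 stayed past it in the same direction under every one of the 20 alternatives that tested them, 63 under every one but the single-library fits, and 0 changed direction. With technical library 1, 2 or 3 alone, 33, 24 and 21 of the 80 did not pass. Of the 11 gene lists, 0 passed camera with an estimated correlation and 10 passed fry, the exception being the ATF4 list. Fry called 14 in all, adding the regulatory T cell, interferon, NRF2 and oxidative phosphorylation lists. The loss under camera does not show correlated genes in each list, since that repeat has fewer degrees of freedom. For the epithelial list the estimated correlation was −0.019, and the unadjusted camera p still went from 0.00296 to 0.0293. Among the 11, that list alone had an estimate below the preset 0.01. The others were at 0.588 (ATF4), 0.567 (NF-kB), 0.526 (ER chaperones), 0.398 (G2/M), 0.36 (cholesterol) and 0.348 (G1/S). Further estimates were 0.245 (HSF1), 0.198 (Wnt), 0.099 (fatty acids) and 0.031 (proteasome). In those lists the preset correlation was below the estimate, so their preset p-values may be too small. Quantile normalization and a 5 FPKM filter each lost the fatty acid list. Of the named genes not past the threshold, 3 passed with all 18 libraries (CD274, CCL20 and CXCL8), and the same 3 without sgHSPB1 replicate 1 and with GC and length trends removed. With a 5 FPKM filter 2 passed (CCL20 and CXCL8), with Ensembl genes alone 2 (CD274 and CCL20), without the trend 1 (CD274) and under quantile normalization 1 (B2M). Among genes and lists not past the threshold, CCL28 turned to 0.004 under quantile normalization, to 0.014 with technical library 1 alone and to 0.010 and 0.009 without sgNC replicate 2 or sgHSPB1 replicate 2 (−0.054 to 0.010 over the replicates left out). Medians of lists near 0 turned too. Apoptosis regulators went to 0.005 (quantile), 0.011 (5 FPKM filter, and again with GC and length trends removed), 0.003 (median-of-ratios), histones to 0.023 (quantile), and NRF2 genes to 0.004 (5 FPKM filter). With a replicate left out, medians ranged from −0.015 to 0.021 for apoptosis regulators, −0.047 to 0.028 for histones, −0.014 to 0.039 for hypoxia genes, −0.023 to 0.010 for ribosomal proteins and −0.205 to 0.033 for mitochondrially encoded transcripts, a list that passed at 0.0146 without sgNC replicate 3. Intestinal genes turned to −0.016 and −0.022 and mesenchymal genes to −0.011 and −0.002. The depth is unknown. On simulated data with 200 changed genes, 34.8% of 1.2-fold changes were found. With 3085 calls in the data the adjusted threshold is looser, so this share does not carry over.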

Other observations

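The lists and genes here were chosen after the changed genes were seen, so their tests describe these data only. In the libraries labelled sgHSPB1, where HSPB1 was higher, cytosolic tRNA synthetases fell: of 19 tested, 12 were lower and 2 higher, with a median log2 fold change of −0.42 (camera adjusted p = 5.31e-05 over 6 such lists, and adjusted p = 0.288 with an estimated correlation). WARS1 fell from 178 ± 6.20 to 100.4 ± 11.18 FPKM (SD, n = 3; −0.82, limma adjusted p = 0.00264) and GARS1 from 278 ± 5.001 to 176 ± 28.7 FPKM (−0.67), while FARSA (0.33) and KARS1 (0.17) were higher and 5 did not pass. All 4 EGF receptor ligands above the filter were lower, AREG from 7.20 ± 0.134 to 3.67 ± 1.115 FPKM (−0.84, limma adjusted p = 0.0134), EREG at −0.52, HBEGF at −0.56 and TGFA at −0.26 (camera adjusted p = 0.0023, and adjusted p = 0.288 with an estimated correlation). With 4 tested members this list is under the minimum of 5 that was set for the fixed lists and was not applied here.

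Of 25 tested autophagy and lysosome genes, 6 were lower and 1 higher (camera adjusted p = 0.0751), among them MAP1LC3B, from 119 ± 3.11 to 90.9 ± 8.22 FPKM (−0.38), GABARAPL1 (−0.40) and WIPI1 (−0.48). Ribosome biogenesis factors split 3 higher to 3 lower of 29 (0.987), and genes of the cornified envelope 1 to 1 of 6 (2 higher and 1 lower adjusted over the list alone; 0.987). For the other 5 lists the counts adjusted over the list alone were the same as over all rows. SPRR2D was the only SPRR gene among those 6. Under the filter, and so untested, SPRR2A was at 0.477 ± 0.0841 and 0.169 ± 0.0237 FPKM, SPRR1B at 0.126 ± 0.0617 and 0.0426 ± 0.0373 FPKM, SPRR2E at 0.124 and 0.111 FPKM, SPRR1A at 0.00861 and 0.0363 FPKM and SPRR3 at 0 and 0.0217 FPKM in sgNC and in the libraries labelled sgHSPB1, and SPRR2F was listed at 0. ER calcium and translocation genes held 4 higher and 2 lower of 23 (0.607), of which the ER calcium pump ATP2A2 rose most, from 38.6 ± 0.818 to 60.6 ± 4.06 FPKM (0.60, limma adjusted p = 0.00259).

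KRT5, a keratin of basal squamous epithelium, was at 1801 ± 65.8 FPKM in sgNC and 1954 ± 47.99 FPKM in the libraries labelled sgHSPB1 (SD, n = 3; 0.12, limma adjusted p = 0.0766), close to the simple-epithelium keratins KRT8 (1704 ± 69.4 and 1977 ± 83.1) and KRT18 (2040 ± 74.2 and 2037 ± 56.2). Its usual partner KRT14 was at 0.292 and 0.384 FPKM and the squamous factor TP63 at 0.0235 and 0.0252 FPKM. Whether reads of another keratin contribute to the KRT5 value was not tested, so it is given as listed and not as a measure of KRT5 expression in this line.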
